A study of Mus musculus with 36 samples.

How the data were processed

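RNA of mouse CD4 T cells was sequenced in 36 libraries. The cells came from spleen, per the labels' protocols, and naive CD4 T cells were obtained with negative-selection beads, which remove cells of other types by their surface markers. For the helper T cell libraries, naive cells were activated on plates coated with an antibody against CD3 and cultured with interleukin 12, interleukin 2 and an antibody against CD28 for the Th1 fate. The culture for the Th2 fate is not given in the sources used here. The mutant strain is named Ets1-SE-KO in the labels, and is called KO below; the coordinates of its deletion are not given in the sources used here. Total RNA was made into strand-specific libraries with a SMARTer Stranded Total RNA-Seq Pico kit and read in pairs on NextSeq or NovaSeq instruments, per the labels' protocols, which do not say which library ran on which instrument.

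The authors deposited a table of raw read counts per gene for each library, as written by the aligner STAR (version 2.5.0a, GRCm38, per the submitters' processing notes). Each table held 45706 genes and 4 summary lines for reads that were unmapped, mapped to several places, outside of genes or ambiguous. These lines named no gene and stayed out of library sizes and tests; they took 63.6% to 76.0% of all reads or pairs tabulated on the strand used. The tables gave counts without strand and for each strand. The strand that held 93.3% to 95.2% of the stranded gene counts was used, and counts without strand were an alternative chosen after the data were examined. Reads of genes with near-identical copies can be lost or split by this counting, so values of such families (the serine protease, interferon-induced GTPase, haemoglobin, heat shock Hspa1 and histone genes) are uncertain. Identifiers were matched to the GENCODE M21 annotation of GRCm38 for symbols and coordinates. This release was not named in the sources used here, and 45143 identifiers matched while 563 did not.

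Groups were taken from titles and labels alone. Of the 36 libraries, 28 formed 10 groups. The other 8 libraries carried a title and a transduction label that named different viruses, so they entered no comparison. Titles give each library a B number and a T number whose meaning is not stated. All libraries of naive cells and of the first Th1 and Th2 cultures share B number 1 and differ in T number. The second Th1 experiment has B numbers 1 and 2. Nothing in the labels says that libraries came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical. In the transduction experiment libraries with the same B number were summed, so that n = 2 in each of its groups. Pairs of libraries within a group were compared by a chi-square test over genes, and none was identical to another or differed by less than sampling noise.

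Total gene counts per library were 5069623 to 5852673 in naive cells, 7311614 to 10256407 in the first Th1 and Th2 cultures, and 1813288 to 6844944 in the labelled libraries of the second Th1 experiment. The 10 most abundant genes took 24.5% to 27.0%, 23.2% to 27.9% and 37.6% to 47.8% of the counts in these sets. Levels are CPM, counts relative to the library's total gene counts, which were scaled by TMM factors unless a level is called raw. Where a group had no count of a gene, a fold is given as a bound, from the pooled raw CPM of the other group against 3 counts in the summed total of the group at 0. Floors cover counting error only, since the tables carry no molecular identifiers, and the intervals given for a share of genes or for a median over genes describe the sampling of genes.

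Differences were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05), and every adjusted p of a gene below is from that test unless another tool is named. Naive cells were fitted alone, the 12 first Th1 and Th2 libraries in one fit of 4 group means, and the second experiment in one fit of its 4 labelled groups. B number did not enter that last fit, except as a block in an alternative. Log2 fold changes are given with their standard errors (SE). Gene lists were tested with camera of limma 3.58.1, at a preset correlation between genes of 0.01 and again with an estimated correlation, and with fry. Adjustment was over the lists of T cell biology of one comparison, and apart from them over the other lists. There were 20 lists of T cell biology and 11 lists of other cells, RNA quality and sex-linked genes. Adjusted p values of lists are from camera with the preset correlation unless stated. The fitting scripts were tested on simulated counts with known changes: at 1.5-fold, 2-fold and 4-fold they recovered 51.8%, 72.5% and 97.1% of changed genes in a simulation of the naive comparison, 64.1%, 78.6% and 98.5% in the first Th1 comparison and 19.7%, 58.2% and 84.1% in the untransduced comparison. Of the calls made there, 3.33%, 3.03% and 7.08% were false, the last above the nominal level. Each simulation was a single draw, with a spread set by a gene's level alone and no effect of B number. The real libraries may therefore have other rates.

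Groups, tests, gene lists, the naming rule and most alternatives were chosen before the data were examined. The naming rule took Ets1, its neighbours and Gm27162, up to 10 genes per direction with the largest log2 fold change among those past the threshold with a mean log2 CPM of at least 3, no overlap between the groups' libraries and an approved-style symbol, up to 4 members of each list with the smallest adjusted p, and 12 helper T cell genes named in advance. The genes printed are a subset of those the rule named, picked after their values were seen; genes outside the rule are marked where they appear. Alternatives fixed beforehand were median-of-ratios size factors, no filter on low counts, DESeq2 1.42.0, protein-coding genes only, a 1.5-fold threshold, only the compared groups in the fit, the replicate number as a block, libraries in place of sums, the second experiment without sex-linked genes, and leaving out each replicate. Added after the data were examined were counts without strand, naive cells without X-linked and Y-linked genes, the second experiment without the WT libraries of B number 1, a joint fit of naive, Th1 and Th2 libraries used for Ets1 alone, and 4 lists of genes made from the comparisons themselves. Plots and the remaining tests used Python 3.11.15 with scipy 1.17.1.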

Results

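Messenger and other RNA was profiled in CD4 T cells of wild-type C57BL/6J mice (WT) and of the Ets1-SE-KO strain (KO), which by its name lacks a super-enhancer, a cluster of regulatory DNA elements, of the gene Ets1. Ets1 encodes a transcription factor of the Ets family that is abundant in T cells. The libraries fell into 3 sets. Naive CD4 T cells gave 2 WT and 2 KO libraries, with 5069623 to 5852673 gene counts each. Th1 and Th2 cells, the helper T cells that make interferon gamma and the interleukins 4, 5 and 13 respectively, gave 3 libraries per genotype and fate, with 7311614 to 10256407 gene counts each. Libraries of a group in both of these sets share B number 1 and differ only in T number. There n counts T numbers, and p-values measure the spread between such libraries, which may be technical. A second Th1 experiment gave 2 untransduced WT, 2 untransduced KO, 4 WT libraries with an empty retrovirus (EV) and 4 KO libraries with a retrovirus carrying Ets1 (Ets1-RV), with 1813288 to 6844944 gene counts each. In that experiment 8 further libraries, whose title and transduction label named different viruses, were not compared.

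Ets1 RNA was lower in KO than in WT cells in the naive and both Th1 comparisons, and the loss was larger in naive cells than in Th1 or Th2 cells of the first experiment. In naive cells it fell by 1.36 on the log2 scale (SE 0.055, adjusted p = 1.73e-86), from 1823 ± 5.11 CPM in WT to 708 ± 16.9 in KO (mean ± SD, n = 2 each). In Th1 cells it was 583 ± 38.1 CPM in KO and 797 ± 53.2 in WT (n = 3 each; log2 fold change -0.45, SE 0.063, adjusted p = 0.000644). In Th2 cells the levels were 716 ± 14.2 and 838 ± 21.7 CPM (n = 3 each), a log2 fold change of -0.23 that did not pass the threshold (SE 0.063, adjusted p = 0.177). The untransduced KO cells of the second Th1 experiment had 232 ± 17.2 CPM against 391 ± 17.4 in WT (n = 2 each; log2 fold change -0.75, SE 0.138, adjusted p = 0.0138). That call was lost without KO library 1 (adjusted p = 0.17), without KO library 2 (0.0639) and without WT library 2 (0.0916). The difference between naive and Th1 cells in the KO effect was itself tested, in a joint fit chosen after the data were examined, and was -0.92 (adjusted p = 1.63e-06); between naive and Th2 cells it was -1.15 (adjusted p = 4.29e-08). Between Th1 and Th2 cells it was -0.22 and did not pass the threshold (adjusted p = 0.428).

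The noncoding gene Gm27162 had no count in any labelled KO library. Gm27162 (ENSMUSG00000099025) is annotated as a lincRNA on chromosome 9, from 32904937 to 32928966 on the minus strand of GRCm38, and Ets1 (ENSMUSG00000032035) lies on the plus strand from 32636221 to 32757820. WT levels of Gm27162 were 3.44 ± 0.735 CPM in naive (n = 2), 4.89 ± 0.887 in Th1 (n = 3) and 2.14 ± 0.453 in Th2 cells (n = 3), and 6.05 ± 1.03 in untransduced Th1 cells of the second experiment (n = 2). Against the limit of 3 counts over the KO group, its raw level was at least 12.4-fold lower in naive, 45.9-fold lower in Th1, 16.9-fold lower in Th2 and 11.1-fold lower in untransduced KO cells. Adjusted p values were 1.67e-07, 2.88e-05, 0.00112 and 0.00624 in that order. With 1 KO library left out the call ended in naive cells (adjusted p = 0.0597 without KO library 1, 0.066 without KO library 2) and in untransduced cells (0.124 without KO library 1). Fli1, another Ets factor gene next to Ets1, had a log2 fold change of 0.21 in naive cells (adjusted p = 0.0367). That call was lost in DESeq2 (0.236) and without KO library 1 (0.209), KO library 2 (0.158), WT library 1 (0.347) or WT library 2 (0.163). Fli1 had log2 fold changes of -0.01 in Th1 (adjusted p = 0.969), 0.07 in Th2 (0.9) and -0.24 in untransduced cells (0.615).

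**Figure D1:**
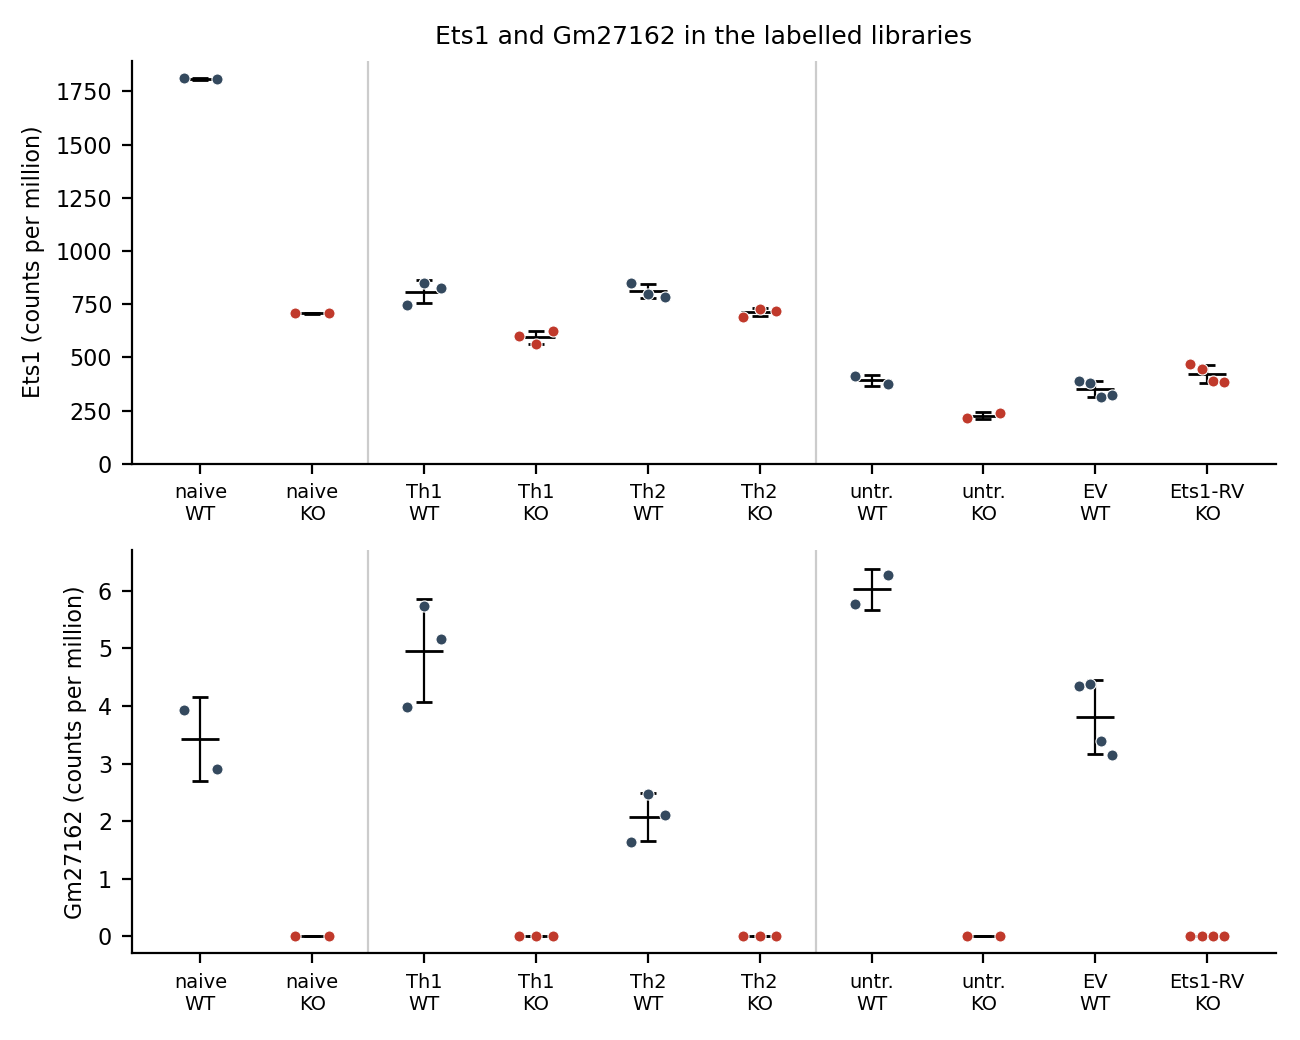
Raw CPM of Ets1 (top) and Gm27162 (bottom) in each labelled library, with the mean and SD of each group; untr. is untransduced, EV is the empty virus, and vertical lines part the 3 sets. Gm27162 is at 0 in all labelled KO libraries and the genotype gap in Ets1 is widest in naive cells.

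Naive KO cells had less RNA of Gbp2, Cd44, Irf4, Prf1 and Adam19 than naive WT cells and more of Ccr9, Nt5e, Cd247 and Hspa1a, and the genotypes also differed in sex-linked RNA and in markers of other cells. The question was what loss of the element does before activation. Gbp2, a GTPase gene induced by interferon gamma, fell from 155 ± 10.8 to 78.9 ± 4.42 CPM (log2 fold change -0.97, SE 0.089, adjusted p = 3.98e-23, n = 2 each). Cd44, the adhesion receptor that marks activated and memory T cells, changed by -1.56 (adjusted p = 2.39e-09), the activation-linked factor Irf4 by -1.56 (5.17e-18) and Prf1, which encodes the pore-forming protein perforin, by -2.04 (3.48e-11). Adam19, a metalloprotease gene, fell from 104 ± 3.77 to 19.97 ± 1.16 CPM (adjusted p = 1.45e-58). Higher in KO were Ccr9, the receptor for a gut chemokine (log2 fold change 3.58, adjusted p = 1.72e-48), Nt5e, the ectonucleotidase CD73 (1.65, 6.51e-25), and Cd247, the zeta chain of the T cell receptor complex (0.73, 5.7e-27). Of 11246 genes tested, 984 were higher and 1003 lower in KO.

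Among the fixed lists, 16 of 19 interferon gamma response genes measured in naive cells were lower in KO and 0 higher, and adjusted over the list alone the counts were the same 16 and 0 (median log2 fold change -0.60, adjusted p = 6.25e-10). Gbp4 (-0.90), Irgm1 (-0.72) and Nlrc5 (-0.56), an activator of MHC class I genes, were among them. The list's adjusted p = 0.372 with an estimated correlation. Of 22 type I interferon response genes 10 were lower and 0 higher, 16 and 1 adjusted over the list alone (median -0.46, adjusted p = 2.58e-04, and adjusted p = 0.372 with an estimated correlation). Of 17 glycolysis genes 6 were lower and 1 higher, also 6 and 1 adjusted over the list alone (median -0.31, adjusted p = 0.0072, and adjusted p = 0.372 with an estimated correlation). TCR signalling genes moved both ways, 11 of 26 higher and 5 lower, 13 and 6 adjusted over the list alone (adjusted p = 0.13). Treg genes likewise had 5 of 12 higher and 2 lower, 5 and 3 adjusted over the list alone (adjusted p = 0.114). Tcf7, a factor of naive T cells, did not pass the threshold (-0.10, adjusted p = 0.206), nor did Il7r, a survival receptor (0.04, 0.773), or Gata3, the Th2 factor (0.23, 0.062).

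RNA quality, other cells and sex also moved with genotype in the naive libraries. Of 15 handling stress genes 11 were higher in KO and 0 lower, and the same counts held adjusted over the list alone (median 0.53, adjusted p = 9.79e-08, and adjusted p = 0.222 with an estimated correlation). The heat shock gene Hspa1a rose from 23.3 ± 3.02 to 341 ± 26.2 CPM (log2 fold change 3.87, SE 0.095, adjusted p = 1.15e-160, n = 2 each). All 4 erythroid and platelet markers measured were lower in KO (4 adjusted over the list alone, adjusted p = 5.54e-04, and adjusted p = 0.222 with an estimated correlation). Of 7 myeloid markers 3 were lower and 1 higher, 3 and 1 adjusted over the list alone (adjusted p = 0.00243, and adjusted p = 0.222 with an estimated correlation). Of 3 B cell markers 2 were lower and 0 higher, 2 and 0 adjusted over the list alone (adjusted p = 0.0126, and adjusted p = 0.222 with an estimated correlation). Xist, the X-inactivation RNA, was at 486 ± 22.8 CPM in WT and at 0 in KO, at least 1740-fold lower, and the Y-linked gene Uty was at least 186-fold higher in KO, so genotype and sex could not be told apart in naive cells. Mitochondrial genes took 12.6% and 12.96% of gene counts in the WT libraries and 14.3% and 16.7% in the KO libraries, and unmapped reads were 35.6% and 35.9% against 30.6% and 33.6%. Summed CD8 T cell markers were at 35.2 CPM in WT and 53.4 in KO, summed gamma-delta T cell markers at 12.3 and 6.09, and summed dendritic cell markers at 3.53 and 10.9, where Itgae, a member that T cells also express, was at 1.72 and 9.12 CPM. The count of 1987 genes fell to 445 without KO library 1, 399 without KO library 2, 1217 without WT library 1 and 1120 without WT library 2.

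**Figure D2:**
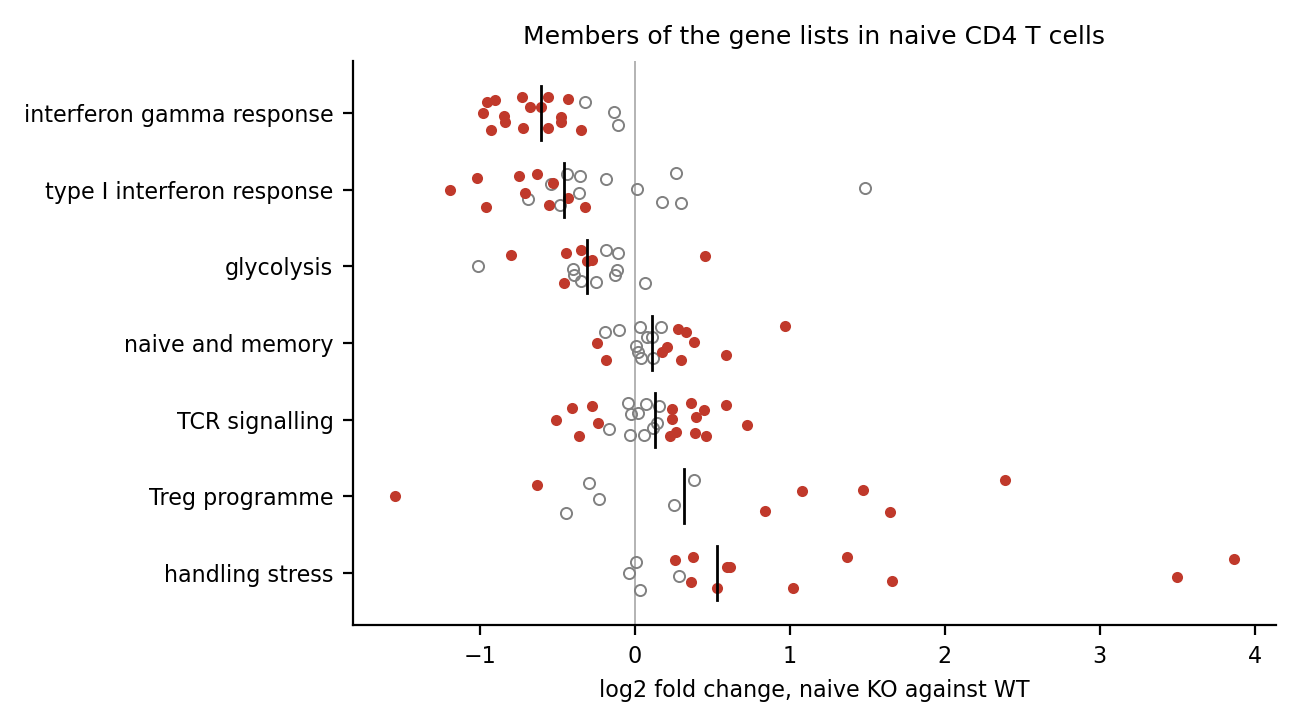
Log2 fold change, naive KO against WT (2 libraries each), of every measured member of 7 gene lists; filled points passed the adjusted threshold, open points did not, and bars mark list medians. Interferon gamma response genes lie below 0, with 16 of 19 filled, and handling stress genes reach 3.87.

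Th1 cells of the KO strain had less RNA of Ifng and of Prf1, Gzmc, Klrd1 and Il18rap than WT Th1 cells, and more of Il10, Pparg and Ccr8. Ifng, the gene of interferon gamma (chromosome 10, 118441046 to 118445892), was at 279 ± 83.4 CPM in KO and 728 ± 218 in WT (n = 3 each; log2 fold change -1.38, SE 0.191, adjusted p = 0.000609). Perforin RNA, from Prf1, was at 11.2 ± 1.71 and 54.1 ± 11.7 CPM (-2.27, SE 0.241, adjusted p = 4.3e-05). The granule protease gene Gzmc changed by -2.15 (adjusted p = 0.00048), the NK receptor gene Klrd1 by -2.19 (0.00121) and Il18rap, a subunit of the interleukin 18 receptor, by -1.47 (0.00177). Higher were Il10, an inhibitory cytokine gene (1.09, adjusted p = 0.0127), Pparg, a nuclear receptor gene (0.75, 0.00206), Ccr8, a Th2 chemokine receptor gene (1.12, 0.00288), the integrin gene Itgae (2.27, 6.47e-05) and Tgfbr1, a receptor for TGF-beta (0.81, 0.000609). Of 12616 genes tested, 272 were higher and 190 lower in KO; the total of 462 fell to 226 without KO library 1 and to 176 without WT library 1.

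Of 28 Th1 programme genes measured, 8 were lower in KO Th1 cells and 1 was higher, 16 and 1 adjusted over the list alone (median -0.42, adjusted p = 1.94e-05, and adjusted p = 0.489 with an estimated correlation). Tbx21, which encodes the Th1 factor T-bet, was at 40.8 ± 1.94 and 58.1 ± 7.25 CPM (n = 3 each) and did not pass the threshold (-0.51, adjusted p = 0.0557), though it did without WT library 3 (0.0373) and in DESeq2 (0.0213). Of 15 cytotoxic granule genes 6 were lower and 1 higher, 9 and 3 adjusted over the list alone (median -0.78, adjusted p = 2.1e-04, and adjusted p = 0.509 with an estimated correlation). The higher one was Gzma (log2 fold change 0.80), singled out after its values were seen. It was also called higher in untransduced KO cells of the second experiment (2.24). Of 20 Th2 programme genes 8 were higher and 0 lower, 11 and 1 adjusted over the list alone (median 0.49, adjusted p = 4.43e-05, and adjusted p = 0.509 with an estimated correlation). The type I interferon list had 1 of 13 lower and 0 higher, 5 and 0 adjusted over the list alone (adjusted p = 0.014, and adjusted p = 0.509 with an estimated correlation). All 4 gamma-delta T cell markers measured were lower, 4 adjusted over the list alone (median -1.97, adjusted p = 2.03e-05, and adjusted p = 0.108 with an estimated correlation), among them Trdc, the constant region of the delta chain, at 2.60 ± 1.25 and 10.7 ± 4.12 CPM (n = 3 each). Of 3 CD8 T cell markers 1 was higher and 0 lower, 1 and 1 adjusted over the list alone (adjusted p = 0.938). It was Cd8b1 (0.75, adjusted p = 0.0421), a call lost without KO library 1 (0.204), KO library 3 (0.0902), WT library 1 (0.144) or WT library 3 (0.134). Of 15 handling stress genes 1 was higher and 0 lower, the same adjusted over the list alone (adjusted p = 0.915). It was Hspa1a, at 1.77 ± 0.989 and 0.203 ± 0.192 CPM (adjusted p = 0.0335), lost without KO library 3 (0.151), WT library 1 (0.162) or WT library 2 (0.0749).

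Among the Th2 genes called in Th1 cells, Gata3, Il13 and Il4 lost their calls without single libraries, while Il10, Pparg and Ccr8 kept theirs under every alternative run. Gata3, the Th2 factor, was at 267 ± 81.2 CPM in KO and 150 ± 58.0 in WT (n = 3 each; log2 fold change 0.84, adjusted p = 0.0227), with libraries of both groups overlapping. Without KO library 1 its adjusted p was 0.131, without WT library 1 it was 0.115 and without WT library 3 it was 0.0604; DESeq2 gave 0.0871. Il13 was at 224 ± 134 and 104 ± 32.3 CPM (1.11, adjusted p = 0.0243), with adjusted p values of 0.139, 0.0521 and 0.0776 without the same libraries and 0.105 in DESeq2. Il4 (0.93, adjusted p = 0.029) gave 0.166, 0.148 and 0.0927 without them. Il5 did not pass the threshold (1.11, adjusted p = 0.129), but did without KO library 3 (0.0432).

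**Figure D3:**
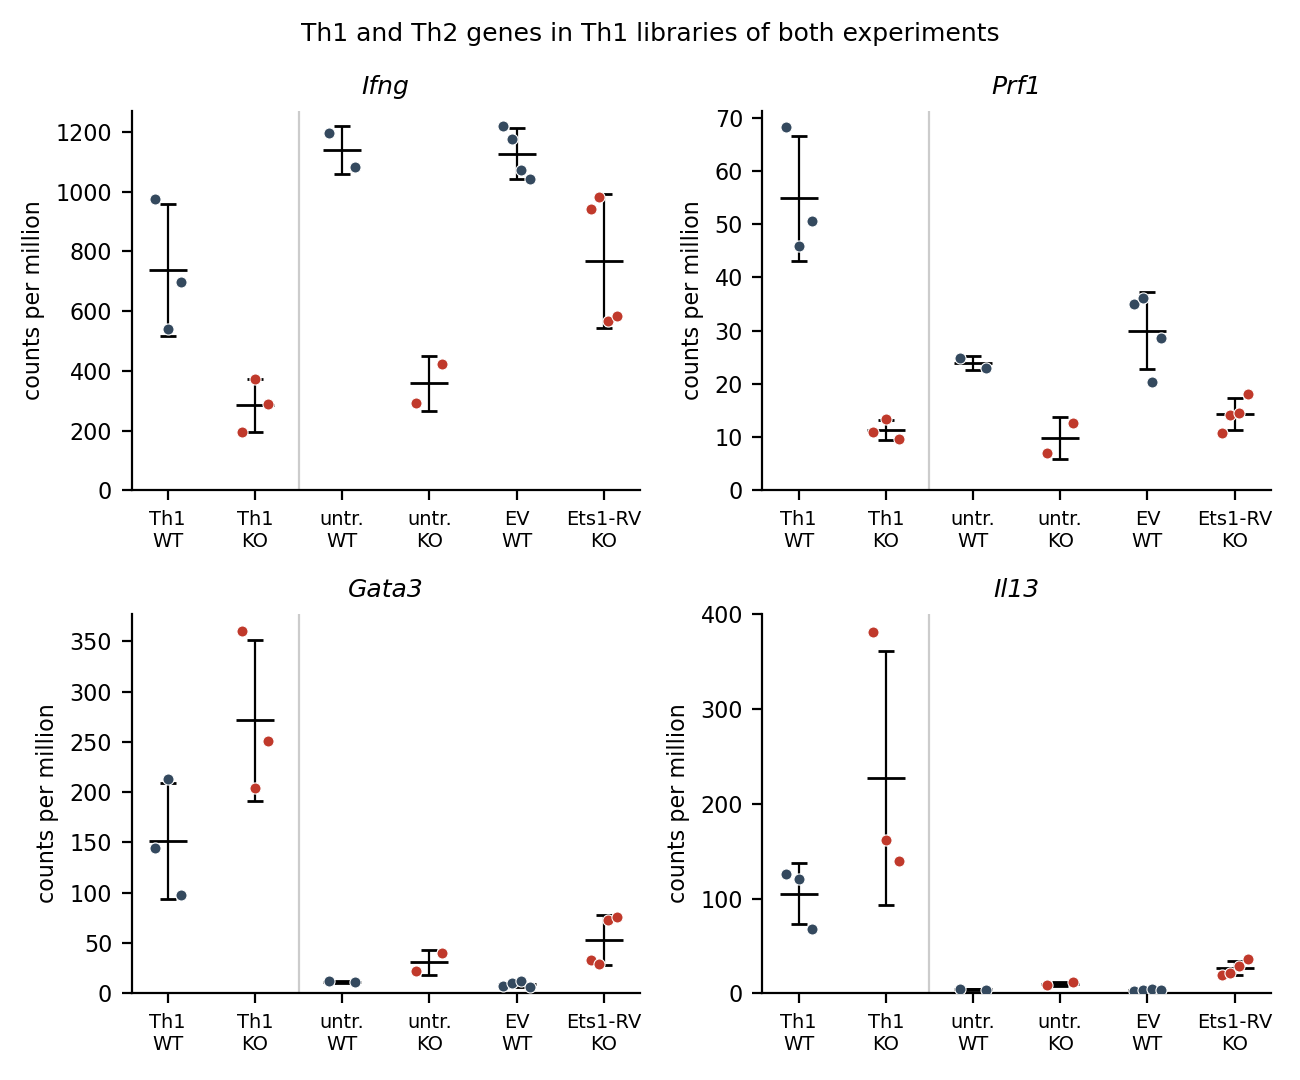
Raw CPM of Ifng, Prf1, Gata3 and Il13 in each Th1 library of the first experiment (left of the line) and the second (right), with the mean and SD of each group; the EV and Ets1-RV groups show 4 libraries each, which were summed per B number in the tests. Ifng and Prf1 lie lower in KO libraries without Ets1-RV than in WT libraries in both experiments.

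In Th2 cells 13 genes were higher and 28 lower in KO, and the Th2 cytokine genes were not among them. Muc13, a transmembrane mucin gene, fell from 26.1 ± 3.00 to 9.88 ± 0.102 CPM (n = 3 each; log2 fold change -1.40, adjusted p = 1.07e-05), Gzmc changed by -2.91 (0.00112) and the phosphatase gene Ppm1j by -1.30 (0.00112). Nhsl1, an actin regulator gene, rose by 2.11 (0.00112), Ubash3b, a phosphatase that restrains T cell receptor signalling, by 0.70 (0.00112) and the GTPase gene Rhoh by 0.64 (0.00363). Gata3 (0.06, adjusted p = 0.966), Il4 (0.06, 0.971) and Il13 (0.08, 0.97) did not pass the threshold. The total of 41 genes fell to 14 without KO library 2, 14 without KO library 3 and 19 without WT library 1.

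In the fixed lists, 1 of 15 cytotoxic granule genes was lower in KO Th2 cells and 0 higher, 6 and 2 adjusted over the list alone (median -0.82, adjusted p = 0.00202, and adjusted p = 0.474 with an estimated correlation). Of 28 Th1 programme genes 0 passed, 2 lower adjusted over the list alone (adjusted p = 0.00416, and adjusted p = 0.474 with an estimated correlation). The Tfh list had 0 of 12, 4 higher adjusted over the list alone (adjusted p = 0.00326, and adjusted p = 0.263 with an estimated correlation). Cell cycle genes had 0 of 24, 0 adjusted over the list alone (median 0.13, adjusted p = 3.85e-05, and adjusted p = 0.474 with an estimated correlation). Gamma-delta T cell markers had 0 of 4, 3 lower adjusted over the list alone (adjusted p = 1.49e-04, and adjusted p = 0.166 with an estimated correlation). The genotype effect was then compared between the fates. In edgeR 0 genes passed the threshold for that difference, with 1226 at an unadjusted p under 0.05, and DESeq2 called 22. Without Th1 KO library 2 the edgeR count was 3 and without Th1 WT library 2 it was 2. Gata3 differed by 0.77 (adjusted p = 0.392) and Il13 by 1.03 (0.392). Ifng did not pass (adjusted p = 0.823), with Th2 levels too low for a firm fold. The Th2 programme list had 0 of 20, 6 higher and 1 lower adjusted over the list alone (median 0.43, adjusted p = 0.00861, and adjusted p = 0.899 with an estimated correlation).

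Th1 and Th2 cells were compared within each genotype to show what the fates differ in. In WT cells Ifng was at 728 ± 218 CPM in Th1 and 1.31 ± 0.978 in Th2 (n = 3 each; log2 fold change 9.11, adjusted p = 1.85e-12), Tbx21 was higher in Th1 by 3.44 (3.12e-10) and the chemokine gene Ccl3 by 5.75 (1.11e-09). Lower in Th1 were Gata3 (-1.47, adjusted p = 1.77e-05), Il13 (-1.26, 0.00151), Pparg (-2.07, 3.02e-10) and the serotonin receptor gene Htr1b (-5.72, 5.49e-13). In all, 1723 genes were higher and 1994 lower in WT Th1 cells. In KO cells 1011 were higher and 1199 lower; the total of 2210 fell to 1380 without Th1 KO library 2 and 1441 without Th2 KO library 2. Tbx21 again differed in KO cells (3.50, adjusted p = 1.05e-09), and so did Ifng (adjusted p = 1.88e-11), at 279 ± 83.4 CPM in Th1 and 0.206 ± 0.183 in Th2 (n = 3 each), where it had 5 counts over the 3 libraries, too few for a firm fold. Gata3 did too (-0.70, adjusted p = 0.0184) but not without Th1 KO library 2 (0.118), Th1 KO library 3 (0.0716), Th2 KO library 2 (0.0563) or Th2 KO library 3 (0.0538), or in DESeq2 (0.0914). Il4 (-0.40, adjusted p = 0.219), Il5 (-0.31, 0.623) and Il13 (-0.23, 0.618) did not pass in KO cells, though without Th1 KO library 1 they did (0.0204, 0.00704 and 0.00131).

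Of 28 Th1 programme genes 21 were higher in WT Th1 than in WT Th2 cells and 2 lower, 24 and 2 adjusted over the list alone (adjusted p = 2.78e-13, and adjusted p = 0.0489 with an estimated correlation). In KO cells the counts were 22 and 2, 23 and 2 adjusted over the list alone (adjusted p = 2.94e-16, and adjusted p = 0.0264 with an estimated correlation). Of 20 Th2 programme genes 18 were lower in WT Th1 cells and 0 higher, 19 and 0 adjusted over the list alone (median -1.05, adjusted p = 2.17e-09, and adjusted p = 0.189 with an estimated correlation). In KO cells 13 were lower and 0 higher, 13 and 0 adjusted over the list alone (median -0.43, adjusted p = 1.15e-07, and adjusted p = 0.172 with an estimated correlation). Of 20 interferon gamma response genes 13 were higher in WT Th1 cells and 2 lower, 14 and 2 adjusted over the list alone (adjusted p = 1.1e-06, and adjusted p = 0.147 with an estimated correlation).

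The second Th1 experiment measured the genotype effect in separate libraries. Untransduced KO cells had 368 ± 93.7 CPM of Ifng against 1136 ± 48.3 in WT (n = 2 each; log2 fold change -1.63, SE 0.214, adjusted p = 0.00163), a call lost without KO library 1 (0.0546). The chemokine gene Ccl3 fell from 45.5 ± 2.15 to 9.41 ± 1.34 CPM (-2.23, adjusted p = 0.000216), Muc13 changed by -2.17 (0.000216) and Rrm2, a subunit of the enzyme that makes deoxyribonucleotides, by -1.47 (0.000216). Higher were Nhsl1 (1.67, adjusted p = 0.000429), Lgals3, the gene of galectin 3 (1.56, 0.000216), Nrn1 (1.56, 0.000187) and the collagen prolyl hydroxylase gene P4ha2 (2.29, 0.00237). Gata3 was at 31.5 ± 12.9 and 11.3 ± 0.564 CPM and did not pass (1.40, adjusted p = 0.0881), nor did Tbx21 (-0.65, 0.124). Of 11072 genes tested 67 were higher and 70 lower; the total of 137 fell to 22 without KO library 1, 34 without KO library 2 and 50 without WT library 2. B number went with sex in this experiment: the 6 labelled libraries of B number 1 had 155 to 240 counts of Y-linked Ddx3y and at most 1 of Xist, and the 6 of B number 2 had 493 to 1623 of Xist and at most 1 of Ddx3y. The main fit left B number out although every group held both B numbers, so differences between B numbers counted as spread. Deviations from group means correlated across genes at 0.489 between WT EV and untransduced WT columns of the same B number. In the other comparisons of this experiment the correlation was 0.0334 to 0.08. With B number as a block, 93 genes were higher and 119 lower, 212 in all. The WT libraries of B number 1 stood apart from those of B number 2, and without them, which leaves WT of a single sex against KO of both, 22 genes were higher and 56 lower.

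Among cell cycle genes 5 of 24 were lower in untransduced KO cells and 0 higher, 20 and 0 adjusted over the list alone (median -0.69, adjusted p = 1.38e-12, and adjusted p = 0.295 with an estimated correlation). Of 28 Th1 programme genes 4 were lower and 0 higher, 11 and 2 adjusted over the list alone (median -0.45, adjusted p = 0.0028, and adjusted p = 0.45 with an estimated correlation). Of 16 Th2 programme genes 4 were higher and 0 lower, 6 and 1 adjusted over the list alone (median 0.33, adjusted p = 0.0381, and adjusted p = 0.641 with an estimated correlation). Glycolysis genes had 0 of 17, 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.0102, and adjusted p = 0.641 with an estimated correlation). Of 3 gamma-delta T cell markers 1 was lower and 0 higher, 2 and 0 adjusted over the list alone (adjusted p = 6.14e-04, and adjusted p = 0.174 with an estimated correlation).

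The genotype effects of the first and second Th1 experiments pointed the same way for most genes called in the first. Of 402 genes called in the first and measured in both, 355 had the same sign in untransduced cells, or 88.3% (exact Clopper-Pearson 95% interval 84.8% to 91.3%), against 59.9% of all 10906 genes. Calls in both numbered 42, of which 41 had the same sign, 23 higher and 18 lower; independent calls would share 1.34 and 1.18 (2-sided Fisher's exact test p = 1.1e-27 for the overlap). The exception, singled out after its values were seen, was Ckap2l, a mitotic spindle gene (0.32 in the first and -1.47 in the second experiment). Cell cycle genes, lower as a list in untransduced KO cells, did not show this in the first experiment. There the 4 members with the smallest adjusted p did not pass: Bub1 (0.24), Ccna2 (0.18), Top2a (0.14) and Ccne1 (-0.31). The log2 fold changes correlated across all genes with a Pearson r of 0.363 and a Spearman rho of 0.276, and genes are not independent replicates. Without the WT libraries of B number 1, 86.4% kept the sign and 18 genes were called in both.

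KO cells given the Ets1 virus were compared with WT cells given the empty virus and with untransduced KO cells, to ask how much of the difference remained. Ets1 was at 419 ± 51.0 CPM in KO Ets1-RV and 348 ± 1.69 in WT EV cells (n = 2 summed libraries each; log2 fold change 0.27, adjusted p = 0.556), and higher than in untransduced KO cells by 0.85 (SE 0.138, adjusted p = 0.0196). Ifng was at 764 ± 277 CPM in KO Ets1-RV, 1118 ± 54.2 in WT EV and 368 ± 93.7 in untransduced KO cells. It passed the threshold against neither WT EV (-0.55, adjusted p = 0.375) nor untransduced KO cells (1.06, 0.0514), the latter passing in DESeq2 (0.000803) and without Ets1-RV B number 2 (0.0235). Ccl3 (1.68, adjusted p = 0.013), Rrm2 (1.20, 0.0103), the mitotic factor Foxm1 (1.24, 0.013) and the transferrin receptor gene Tfrc (1.07, 0.013) were higher in KO Ets1-RV than in untransduced KO cells. Nrn1 was lower (-0.93, adjusted p = 0.013). In that comparison 14 genes were higher and 7 lower, and 45 passed with B number as a block. The total of 21 became 7 without Ets1-RV B number 1, 5 without Ets1-RV B number 2, 38 without untransduced KO library 2 and 0 without untransduced KO library 1, where Ets1 had an adjusted p of 0.425, Ccl3 0.386, Rrm2 0.244, Foxm1 0.445, Tfrc 0.386 and Nrn1 0.244. Without Ets1-RV B number 1 the adjusted p was 0.177 for Ets1, 0.0724 for Foxm1, 0.0988 for Tfrc and 0.122 for Nrn1, and without Ets1-RV B number 2 it was 0.0533 for Ets1, 0.0533 for Foxm1 and 0.092 for Nrn1.

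Between KO Ets1-RV and WT EV cells, Il13, Gata3 and Lgals3 were higher and Prf1, Gzmc and Trdc lower. Il13 was at 25.9 ± 7.62 and 3.38 ± 1.39 CPM (n = 2 each; log2 fold change 3.05, SE 0.297, adjusted p = 0.000321) and Gata3 at 52.5 ± 30.0 and 8.58 ± 1.02 CPM (2.65, SE 0.336, adjusted p = 0.00248). In untransduced KO cells these genes were at 10.4 ± 2.05 and 31.5 ± 12.9 CPM, lower than with Ets1-RV, without passing the threshold for that change (Il13 1.38, adjusted p = 0.0741, and Gata3 0.83, 0.379). Net of transduction the changes were 1.80 for Il13 (adjusted p = 0.913) and 1.25 for Gata3 (0.991). Prf1 changed by -1.06 (adjusted p = 0.033), Gzmc by -2.18 (0.036) and Trdc by -2.94 (0.00332), while Lgals3 was higher by 1.20 (0.00248). Gm27162 was again without a count in KO, at least 19.8-fold lower. WT libraries of B numbers 1 and 2 stood apart from each other, and neither was shown to be the odd one. TMM factors of the WT EV columns were 1.114 for B number 1 and 0.9135 for B number 2, against 1.005 and 1.014 in KO Ets1-RV. A fit without all WT libraries of B number 2 was not run. The fit without those of B number 1 leaves a single WT EV column, so calls lost there cannot show that B number 1 was faulty. Without the WT libraries of B number 1, which stood apart, 0 genes passed in edgeR: the adjusted p was 0.0645 for Il13, 0.134 for Gata3, 0.384 for Prf1, 0.587 for Gzmc, 0.17 for Trdc, 0.0975 for Lgals3 and 0.13 for Gm27162. The 33 genes higher and 29 lower, 62 in all, became 95 with B number as a block, 10 without Ets1-RV B number 2 and 23 without EV B number 1. Prf1 was lost without Ets1-RV B number 1 (0.146), without Ets1-RV B number 2 (0.101) and without EV B number 1 (0.231). Gzmc was lost without the same columns (0.136, 0.112 and 0.446), Gm27162 without Ets1-RV B number 2 (0.0574) and Trdc without EV B number 1 (0.053).

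Of 11 cytotoxic granule genes 2 were lower in KO Ets1-RV than in WT EV cells and 1 higher, 3 and 1 adjusted over the list alone (adjusted p = 0.236). Of 16 Th2 programme genes 3 were higher in KO Ets1-RV than in WT EV cells and 0 lower, 8 and 1 adjusted over the list alone (median 0.44, adjusted p = 2.79e-05, and adjusted p = 0.467 with an estimated correlation). Cell cycle genes had 0 of 24, 0 adjusted over the list alone (median -0.22, adjusted p = 7.46e-05, and adjusted p = 0.467 with an estimated correlation). Against untransduced KO cells 3 of the 24 were higher and 0 lower, 13 and 0 adjusted over the list alone (median 0.51, adjusted p = 2.11e-11, and adjusted p = 0.349 with an estimated correlation). Of 3 gamma-delta T cell markers 2 were lower than in WT EV cells and 0 higher, 2 and 0 adjusted over the list alone (adjusted p = 6.62e-07, and adjusted p = 0.0531 with an estimated correlation).

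The 402 genes of the first Th1 comparison, signed by their direction there, had a median log2 fold change of 0.43 in untransduced KO against WT cells (bootstrap 95% interval over genes 0.38 to 0.48) and of 0.29 in KO Ets1-RV against WT EV cells (0.26 to 0.36), with 355 of 402 in the first-experiment direction in each. In KO Ets1-RV against untransduced KO cells the median was -0.11 (-0.14 to -0.065), and net of transduction it was -0.066 (-0.12 to -0.040). By direction, the genes lower in the first experiment had medians of 0.12 and 0.14 in these contrasts and the genes higher there -0.091 and -0.0075; whether the directions differ was not tested. In edgeR 0 genes differed between WT EV and WT untransduced cells, with 268 at an unadjusted p under 0.05 and 0 in DESeq2, and 5 passed without untransduced WT library 1. The virus contrast net of transduction, which sets the change in KO with Ets1-RV against the change in WT with EV, had 0 genes past the threshold in edgeR, 528 at an unadjusted p under 0.05 and 3 in DESeq2. Ets1 was among those tested (1.02, adjusted p = 0.218). The count became 1 without Ets1-RV B number 2 and 4 without untransduced KO library 2. The numbers at an unadjusted p under 0.05 in these last 2 contrasts, 268 and 528, were both below a share of 0.05 of the 11072 genes tested. They show no excess of small p-values. No labelled KO group received the empty virus, so Ets1 and transduction could not be told apart within KO cells.

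**Figure D4:**
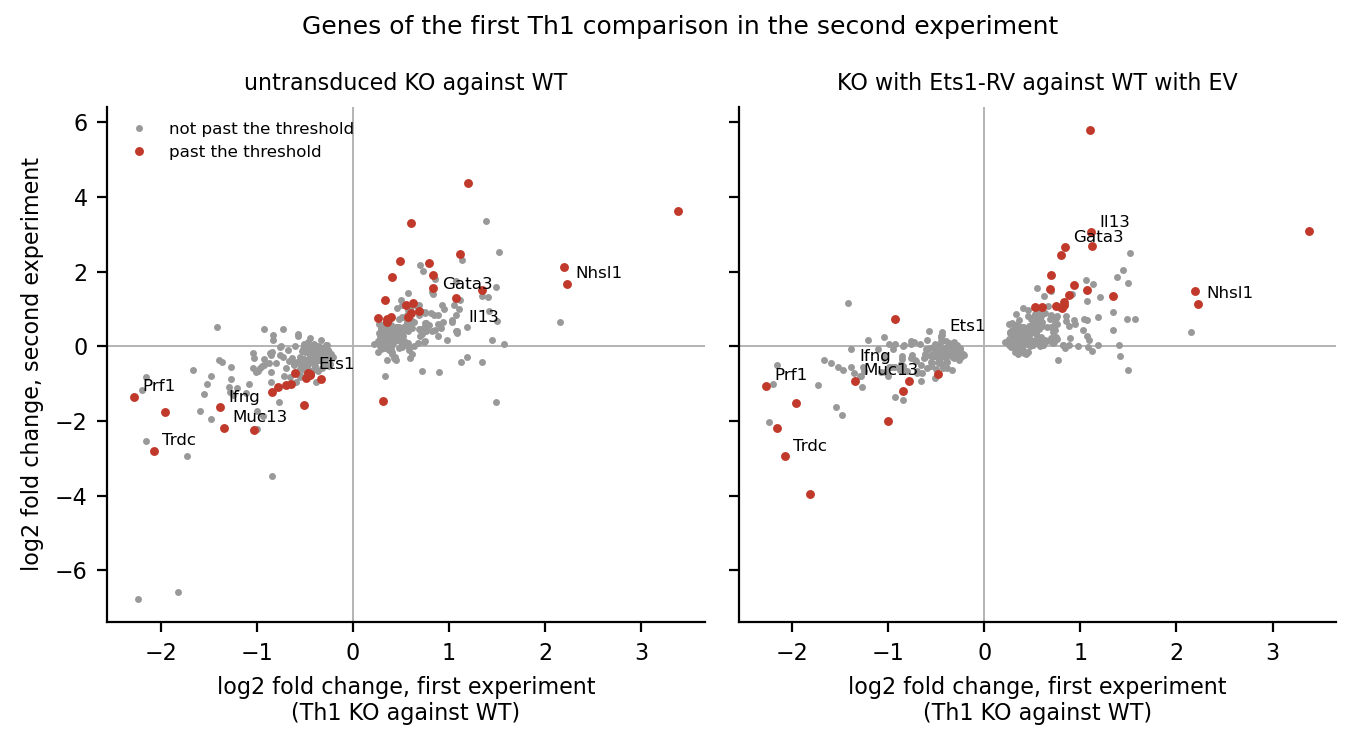
Log2 fold changes of the genes called in the first Th1 comparison (Gm27162 left out), first experiment on the horizontal axis; the vertical axis is untransduced KO against WT (left) or KO with Ets1-RV against WT with EV (right). Red points passed the threshold in the second experiment, and in each panel 355 of 402 genes, Gm27162 included, have the same sign as in the first.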

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

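All tests in this part were chosen after the results were seen, except the planned search for single libraries far from their group.

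Gm27162, without a count in every labelled KO library, had counts of 5, 9, 17 and 13 in the 4 libraries titled KO with the empty virus, a signal in libraries that entered no comparison. The 4 libraries titled WT with the Ets1 virus had none, so the Gm27162 count of 8 of the 8 libraries went against the genotype of their title. Ets1 levels went against the virus of the title in 8 of 8 as well: those titled empty virus lay above every labelled WT EV library, at 565 to 632 raw CPM, and those titled Ets1 virus lay below every labelled KO Ets1-RV library, at 189 to 269. WT RNA carried over into the libraries titled KO was excluded as the whole cause, because at the lowest WT level of the experiment 44.5 Gm27162 counts were to be found over the 4 libraries titled WT, where 0 were seen. These counts argue against the titles as given, in genotype and in virus, for all 8 libraries. A candidate explanation is that the titles of both sets of 4 were exchanged while the transduction label, which names the other virus, is right. The labels alone cannot settle it, and no biological explanation was tested.

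The KO effect on Ets1 differed between cell states in the test of the difference itself, by -0.92 on the log2 scale between naive and Th1 cells and by -1.15 between naive and Th2 cells. Naive and cultured cells are also separate sets of libraries, and the naive genotypes differ in sex-linked RNA.

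Tcrg-C2, the constant region of a gamma chain, had 1 of the 4 WT EV libraries far from the other 3, with a gap of 0.941 of the group's range, above Dixon's 95% critical value for a group of 4. Chance alone puts about 1 in 20 groups of 4 independent libraries past that value. These libraries come in pairs of the same B number, so that rate may not hold. In each group of 4, 39 values were tested, the total gene count among them.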

How the results depend on the processing

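Counts without strand, naive cells without X-linked and Y-linked genes and the second experiment without the WT libraries of B number 1 were chosen after the data were examined; all other alternatives were fixed before. Of 227 results for named genes 179 passed the threshold, 97 of these kept direction and side of the threshold under every alternative run, 82 were lost under at least 1, and of the 48 that had not passed 24 were gained under at least 1; 0 reversed. By setting, leaving out 1 replicate ended 190 of 1176 values and gained 8, the second experiment without WT B number 1 ended 25 of 69, DESeq2 ended 12 of 227 and gained 4, no filter ended 1 and gained 21, and median-of-ratios size factors changed 0. A change of direction was counted as reversed only where the main or the alternative fit passed the threshold. In a fit with a single library left in a group, that library was assumed to vary like the other groups. The cause of these changes was not tested, except that leaving libraries out, a fold threshold and the use of libraries as replicates change the sample number or threshold by construction. The second experiment had the lowest depth and recovered 19.7% of 1.5-fold changes in simulation.

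The number of genes past the threshold moved as follows. With one replicate left out it was 399 to 1217 in naive cells, 176 to 469 in Th1, 14 to 50 in Th2, 2787 to 3706 in WT Th1 against Th2, 1380 to 2046 in KO Th1 against Th2, 22 to 92 in untransduced cells, 10 to 64 in KO Ets1-RV against WT EV, 0 to 38 against untransduced KO, 0 to 3 for the difference between fates, 0 to 5 for WT EV against untransduced WT and 0 to 4 net of transduction. With DESeq2 it was 865 in naive cells, 78 in Th2, 22 for the difference between fates, 40 in KO Ets1-RV against untransduced KO and 3 net of transduction. At 1.5-fold or more it was 844 in naive cells, 224 in Th1, 1633 in WT Th1 against Th2 and 980 in KO Th1 against Th2. Without a filter on low counts it was 835 in Th1, 224 in Th2, 213 for the difference between fates, 416 in untransduced cells, 257 in KO Ets1-RV against WT EV, 17 in WT EV against untransduced WT, 212 in KO Ets1-RV against untransduced KO and 29 net of transduction. With only the compared groups in the fit it was 67 in Th2 and 7 in KO Ets1-RV against untransduced KO. With the replicate number as a block it was 63 in Th2, 212 in untransduced cells, 95 in KO Ets1-RV against WT EV, 45 against untransduced KO and 1 net of transduction. With libraries as replicates it was 266 in untransduced cells, 441 in KO Ets1-RV against WT EV, 126 against untransduced KO and 6 net of transduction. Net of transduction it was 1 with protein-coding genes alone and 1 without sex-linked genes. Without WT B number 1 it was 78 in untransduced cells, 0 in KO Ets1-RV against WT EV and 1 in WT EV against untransduced WT.

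At an adjusted p of 0.01 the share of first-experiment genes with the same sign in untransduced cells was 96.9%, and their signed median in KO Ets1-RV against WT EV cells was 0.55; at 1.5-fold or more that median was 0.62. With the same choices the signed median was 0.71 and 0.80 in untransduced KO against WT, -0.20 and -0.14 in KO Ets1-RV against untransduced KO, and -0.17 and -0.17 net of transduction. The number of list tests past the threshold at the preset correlation was 50, against 2 with an estimated correlation. Of 20 lists per comparison, 4 passed at the preset correlation in naive cells, 5 in Th1, 6 in Th2 and 4 in untransduced cells. In KO Ets1-RV cells 6 passed against WT EV and 3 against untransduced KO. Not all of these lists are named above.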

Other observations

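Tests in this part were chosen after the results were seen, with the following exceptions. The counts over other splits of the libraries and the planned fits of Ifng in KO Ets1-RV against untransduced KO cells were fixed before. How both are read here was written afterwards.

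A part of the genes called in KO Th1 cells was also called in naive cells, which had not been cultured. Of 152 genes lower in KO Th1 cells and measured in naive cells, 76 were lower in naive KO cells and 8 higher, 85 and 11 adjusted over the list alone (median log2 fold change -0.29, adjusted p = 1.57e-13, and adjusted p = 0.131 with an estimated correlation). Of 179 genes higher in KO Th1 cells, 62 were higher in naive KO cells and 7 lower, 71 and 11 adjusted over the list alone (median 0.21, adjusted p = 1.15e-07, and adjusted p = 0.0484 with an estimated correlation). Genes over 2-fold lower in WT Th1 than in WT Th2 cells tended upward in untransduced KO Th1 cells, with 5 of 234 higher and 1 lower, 17 and 4 adjusted over the list alone (median 0.24, adjusted p = 1.37e-04, and adjusted p = 0.0043 with an estimated correlation). These lists were made from the data themselves, and the naive genotypes differed in sex. The opposite list, of genes over 2-fold higher in WT Th1 than in WT Th2 cells, was also tested and is not reported here.

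The 4 libraries titled KO with the empty virus, which carry an Ets1 virus label, had 1234 to 1442 raw CPM of Ifng and 2.65 to 4.90 of Gm27162. The 4 libraries titled WT with the Ets1 virus, which carry an empty vector label, had 374 to 443 raw CPM of Ifng and 0 of Gm27162. Their Gata3 was at 27.4 to 62.8 raw CPM and their Il13 at 13.8 to 20.8. Labelled WT EV libraries had 5.97 to 11.9 and 2.28 to 4.24, and labelled KO Ets1-RV libraries 29.6 to 76.2 and 19.7 to 35.8. These libraries had 1598409 to 6131170 gene counts each.

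Lower interferon gamma response RNA in naive KO cells may reflect fewer cells that sense or make interferon, a difference in sex, or RNA of other cells. B cell, myeloid, erythroid and platelet markers lost 122 CPM in KO where the summed level of the interferon gamma response genes fell by 700.3 CPM, a ratio of 0.175, while dendritic cell markers, outside this sum, were 7.36 CPM higher in KO. How much interferon-induced RNA such cells carry per marker was not measured, so RNA of other cells remains open. The bead selection is meant to remove such cells, but RNA of their markers was still measured. B cell markers summed to 292.3 CPM in naive WT and 202.7 in naive KO cells. Sex remains open too and cannot be told apart from genotype, since 0 of the genotypes had naive libraries of both kinds of sex-linked counts. The first explanation was not tested, and higher handling stress genes in KO also remain open.

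Lower RNA of Ifng and of most called cytotoxic granule genes, Gzma excepted, came with lower gamma-delta T cell markers in KO Th1 cells. Fewer gamma-delta T cells in the KO cultures is therefore a candidate explanation. For the Th2 programme genes, a smaller share of such cells in the RNA would by itself raise Cd4 along with them. Cd4, chosen after its values were seen, had a log2 fold change of -0.22 (SE 0.081) in KO Th1 cells. This argues against a smaller share alone as the whole cause for these genes, provided that Cd4 itself does not respond to genotype. Cd4 cannot decide whether fewer gamma-delta T cells acted on the other cells, since such an effect need not change Cd4. For Ifng, fewer gamma-delta T cells cannot be told apart from other causes. In KO Ets1-RV cells Trdc stayed low while Ifng against untransduced KO cells had an adjusted p of 0.0514. That contrast passed in DESeq2 (0.000803), with B number as a block (0.042) and without Ets1-RV B number 2 (0.0235), but not with only the compared groups in the fit (0.112), without Ets1-RV B number 1 (0.411) or without untransduced KO library 1 (0.656), over a range of 2.19e-12 to 0.656. The bead selection for CD4 T cells would remove most gamma-delta T cells, though their markers still summed to 12.3 CPM in naive WT and 6.09 in naive KO cells. A direct effect of Ets1 on these genes was not tested.

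Other splits of the same libraries were counted for the first experiment. For KO against WT, 1 of 10 splits of the Th1 libraries gave as many genes, the real one with 462, and the highest other gave 2; for Th2 cells 1 of 10, with 41 against 0. For Th1 against Th2 cells it was 1 of 10 in WT (3717 against 0) and 1 of 10 in KO (2210 against 0). With 10 splits a share under 0.05 cannot be had. For the difference of the genotype effect between the fates, all 100 of 100 drawn splits gave as many genes, which the real count of 0 fixes in advance, so this count decides nothing. The highest other gave 474 and was the split that kept the 3 Th1 KO libraries and exchanged the genotypes of the Th2 libraries, so that both genotype effects added up.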
